A study of Chrysanthemum x morifolium with 6 samples.

How the data were processed

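RNA was sequenced from roots of the chrysanthemum cultivar jinba, from seedlings given 100 mM salt water or purified water and collected 24 h after treatment. The labels give 3 biological replicates per treatment, so the data are 6 libraries in 2 groups. All 6 libraries were used and every sample column was matched to its label by treatment and replicate number. Per the labels, total RNA went into Illumina TruSeq libraries and was sequenced on an Illumina HiSeq.

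The authors' processing notes name Bowtie2 2.0.6 and TopHat2 2.0.12 without saying what each was used for. The assembler, the counting tool, the annotation tools and their versions are not given in the sources used here. No reference genome was used here, so chromosome positions are not given and each feature is a sequence cluster. Clusters with near-identical sequences can be copies or alleles of 1 gene, and reads can be shared between them.

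The deposited table of all clusters holds FPKM (fragments per kilobase of cluster and per unit of mapped fragments, the usual fragments-per-kilobase-per-million measure) for 469059 clusters, with no annotation. A further deposited table holds expected counts, FPKM, cluster length, database match score and annotation text for clusters that the authors assigned to a transcription factor or regulator family. It holds 10744 clusters (2.29% of all) in 10935 rows and 81 families, of which 191 rows repeat a cluster. In it, 17 clusters stand in 2 families, and 49.3% of the deposited counts are not whole numbers. The largest difference in FPKM of these clusters between the tables was 0. The authors' log2 ratio, q value and UP or DOWN call for salt against control stand in the same table, and the tool behind them is not named. Gene names in the text are those of the best Swiss-Prot match and do not establish orthology.

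Because the count table covers part of each library, its column sums are not the depth. Depth was recovered from the ratio of deposited count to FPKM over clusters with at least 200 counts and at least 1000 bases. It came to 16.2, 20.1 and 15.9 M fragments (M for mega) for control 1 to 3 and 14.7, 16.1 and 12.8 M for salt 1 to 3. Counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3), by the quasi-likelihood F-test of salt minus control. The filter was filterByExpr at its defaults, and library sizes were the recovered depth times TMM factors from the FPKM table of all clusters. Levels are CPM (counts-per-million) of this effective library size, given as mean ± SD over n = 3 libraries per group. The SE beside a log2 fold change is the approximate SE implied by the F statistic. FPKM of all clusters were tested with limma 3.58.1 with an intensity trend on log2(FPKM + 1), for clusters with FPKM of at least 1 in at least 3 libraries. All p-values across clusters were adjusted by Benjamini-Hochberg and clusters were called at an adjusted p under 0.05. They were counted again with an absolute log2 fold change of at least 1. These p-values measure the spread between libraries given as biological replicates.

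Families and 32 function lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, and again with an estimated correlation and with fry. A negative estimated correlation was set to 0. With an estimated correlation, camera takes its degrees of freedom from the 6 libraries, so a lost call can also reflect low power. Fry's directional p tests whether the members move on balance one way and does not compare them with other clusters. Shares of called clusters per family were compared with all other tested clusters by Fisher's exact test, two-sided, for higher and lower calls separately. P-values were adjusted over the families or over the function lists. The function lists, tests, thresholds, rule for named genes and most alternatives were chosen before the data were examined. Family membership is the deposited family name, because the name patterns chosen beforehand missed or mixed some deposited families. Function lists were matched to all annotation text. In a table of regulators, the lists for enzymes, transporters and structural proteins are filled through secondary text and do not measure their pathways.

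The annotation also names the organism of each best match. Clusters were grouped as plant-matched (6563), non-plant-matched (1162) or unresolved (3019). A cluster is non-plant-matched when its NR match is an oomycete, alga or protist without a seed plant match in Swiss-Prot, or when it has no NR match and a fungal, oomycete or algal Swiss-Prot match. Of 9221 clusters with an NR match, 0 had a fungal one, so fungi enter this class through Swiss-Prot alone. The genera were assigned by hand to organism groups for 245 genera, after the counts per genus in each group of libraries had been seen. All comparisons that use these classes were therefore chosen after seeing the data. They include TMM over plant-matched clusters, for all clusters or for plant-matched clusters alone, and counts of plant-matched clusters summed over a shared NR match. Matching function lists to protein names alone was also added after seeing the data.

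The rule for named genes takes called clusters with an absolute log2 fold change of at least 1, a mean count of at least 20, no overlap between groups and a named protein. Of these it takes the 10 largest rises and the 10 largest falls, 1 per name. It adds the 3 annotated clusters with the highest level. For each list called by camera and each list of other-tissue markers it adds up to 4 members, those with the lowest p and the highest level. The rule gave 121 clusters, and the text names those of the lists about hormones, the clock, nutrition, histones and stress, with few from the rest. A cluster at 0 counts in a whole group has its fold change given as a bound against 3 counts over that group. Such bounds cover counting error only. For lists with at least 5 members tested under a scaling, the medians were the same with such clusters at their bounds. A named cluster with 1 to 3 counts in a group is given as a ratio of group counts scaled to depth, with an exact binomial interval that covers counting error alone.

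Alternatives were DESeq2 1.42.0 size factors and Wald test, no filter and a stricter filter, column sums with TMM over the count table, and recovered depth with no composition factor. They also included limma on the same clusters, another pseudocount, other FPKM filters and scales, a replicate block and leaving out each library in turn. The titles number the replicates 1 to 3 in both groups. Deviations from the group mean were compared between same-numbered libraries to see whether the numbers pair the samples, and the replicate block was run as an alternative only. Counts were simulated with real count means, an assumed dispersion and no shift in composition. On them edgeR tested 5272 clusters and recovered 96% of 2-fold and 100% of 4-fold rises. It recovered 70% of falls to 0.5 and 100% of falls to 0.25, with 6 false calls. On simulated log2 FPKM of 184306 clusters, limma recovered 14%, 54%, 4% and 48% of the same changes, with 2 false calls. Camera and Fisher's exact test each called the shifted list among 20 simulated lists and 0 others. Those lists were random clusters with independent noise. The 0 therefore does not speak for real lists, whose members can be related and move together. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 served for tables and figures.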

Results

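The data describe gene expression in roots of 1-month-old chrysanthemum seedlings of the cultivar jinba, in 3 libraries from plants watered with purified water (control) and 3 from plants given 100 mM salt water. Roots were collected 24 h after treatment. The series asks how chrysanthemum roots respond to salt. Depth was 17.4 ± 2.35 M fragments (M for mega) in control and 14.5 ± 1.68 M in salt (SD, n = 3). The count table of transcription factors and other regulators summed to between 755881 and 957690 counts in control and between 515384 and 652098 in salt. That was 4.75% ± 0.0070 of the depth in control and 4.07% ± 0.051 in salt (SD, n = 3).

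The libraries grouped by treatment. Across 184306 expressed clusters, FPKM profiles correlated at r = 0.903 to 0.915 between control libraries, 0.851 to 0.879 between salt libraries and 0.598 to 0.621 between groups. These are correlations across clusters, which are not independent replicates. The first principal component carried 67.5% of the variance and separated the groups, and the second, with 11.3%, separated salt 1 (score 235) from salt 2 (-76.8) and salt 3 (-156). The 10 most abundant clusters of each library took 1.94% ± 0.130 of FPKM in control and 3.93% ± 0.758 in salt (SD, n = 3).

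**Figure D1:**
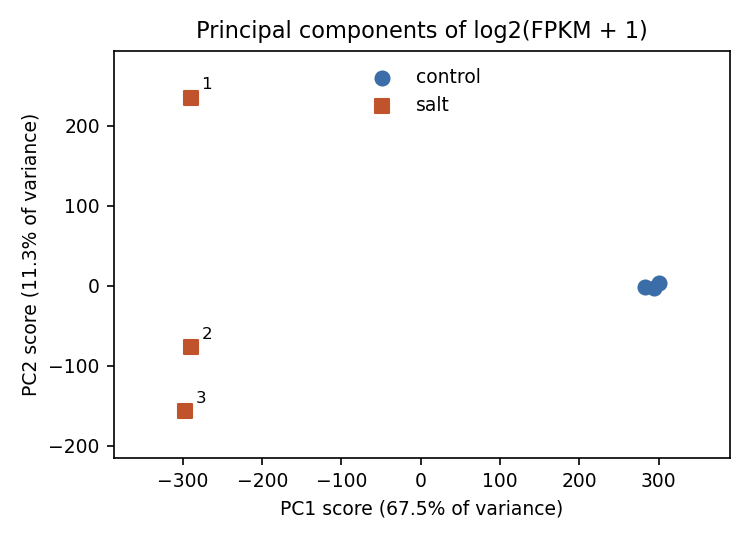
Principal component scores of the 6 libraries from log2(FPKM + 1) of 184306 clusters, with control as circles and salt as squares numbered by replicate. The groups separate on the first component (67.5% of variance), and the second (11.3%) spreads the salt libraries from -156 to 235.

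In the table of all clusters, limma called 42096 clusters higher and 52380 lower in salt, of which 34506 and 38860 changed at least 2-fold. Of the tested clusters, 60.05% had no overlap between the groups, against 10% by chance. Among unannotated clusters, Cluster-71316.300210 was listed at 0 FPKM in every control library and at 512 ± 208 FPKM in salt, and Cluster-71316.300376 at 0 and at 214 ± 163 FPKM (SD, n = 3; limma adjusted p = 4.3e-05 and 2.2e-04). Cluster-71316.161923 fell from 132 ± 23.1 to 0.0733 ± 0.127 FPKM and Cluster-71316.138755 from 403 ± 94.9 to 5.77 ± 9.99 FPKM (SD, n = 3; limma adjusted p = 2.7e-05 and 0.0026). The last cluster was listed at 0 in salt 1 and salt 2 and at 17.3 FPKM in salt 3, and Cluster-71316.300376 at 401.65, 136.45 and 104.66 FPKM in salt 1 to 3, so single libraries carried much of these means. What these 4 clusters encode is unknown, because this table has no annotation. The median log2 fold change of all tested clusters was -0.25, and rescaling FPKM by the median of ratios moved it by 0.16, to 47904 higher and 43477 lower calls, so which direction had more calls depended on the scale.

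Among annotated regulators, 36 of 62 tested clusters of the Tify (jasmonate ZIM-domain) repressors were called higher in salt and 3 lower, while 38 of 65 auxin response factor (ARF) clusters were called lower and 1 higher. In the RWP-RK family, which holds NIN-like proteins, 59 of 138 were called lower and 8 higher, and in the homeodomain family 63 of 134 and 14. Camera called each of these families at the preset correlation but none with an estimated correlation (adjusted p = 0.27, 0.070, 0.14 and 0.10). TIFY 7 (Cluster-71316.116876) rose from 7.90 ± 0.306 to 54.97 ± 6.52 CPM (counts-per-million), 6.96-fold, and histone H2A.1 (Cluster-71316.173270) rose from 14.3 ± 0.370 to 45.998 ± 3.36, 3.21-fold (SD, n = 3; edgeR). Auxin response factor 11 (Cluster-71316.127003) fell from 50.2 ± 0.863 to 10.4 ± 1.46 CPM and NLP7 (Cluster-71316.176179), a regulator of nitrate responses, from 14.97 ± 0.975 to 3.06 ± 0.347 (SD, n = 3; edgeR).

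Of 5284 regulator clusters tested, edgeR called 1261 higher and 1549 lower in salt, and 1086 and 1177 of them changed at least 2-fold. At an unadjusted p under 0.05 the count was 3143. The median log2 fold change was -0.36. It moved by 0.30 with DESeq2 size factors, by 0.22 with column sums, by -0.14 with no composition factor and by 0.58 with TMM over plant-matched clusters. Higher calls then made up 57.2%, 54.1%, 39.7% and 68.4% of all calls, against 44.9%, so the balance of rises and falls turned with the scaling. The authors' own table calls 1446 clusters UP and 1098 DOWN, of which 1067 and 984 were tested. Of these, 1048 were called higher and 979 lower with at least a 2-fold change, and 0 were called the opposite way at that threshold. Of 3233 tested clusters that the authors did not call, 38 were higher and 198 lower at the same threshold.

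The organisms of the best matches also differed between groups. Clusters matched to fungi, oomycetes, algae or protists took 0.819% ± 0.037 of the table's counts in control and 4.62% ± 1.06 in salt (SD, n = 3), with 3.40% in salt 1, 5.29% in salt 2 and 5.17% in salt 3. Scaled to depth, their counts were 4.82 times higher in salt, while those of plant-matched clusters were 0.784 times the control level (exact permutation test, two-sided, p = 0.1 for each, the smallest that 3 against 3 libraries can give). Of 405 tested non-plant-matched clusters 332 rose and 2 fell, and of 3814 plant-matched clusters 457 rose and 1359 fell. Clusters near 0 in 1 group pass the filter through the other group alone, which adds to such counts. Unresolved clusters went from 7.82% ± 0.034 of the counts in control to 11.8% ± 1.64 in salt (SD, n = 3), and of 1065 tested 472 rose and 188 fell. When plant-matched clusters were tested alone with their own TMM factors, 807 of 3748 rose and 670 fell, and 746 and 703 did so without salt 1. Groups are therefore given under the scaling to all clusters and, for plant-matched clusters, under their own scaling, which was chosen after seeing the data. No list's call held with an estimated correlation, with lowest adjusted p = 0.065 among 71 families and 0.12 among 27 function lists. Those tests had 13 and 8 unadjusted p-values under 0.05, against 22 and 12 lists called by camera at the preset correlation and 58 and 22 by fry.

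**Figure D2:**
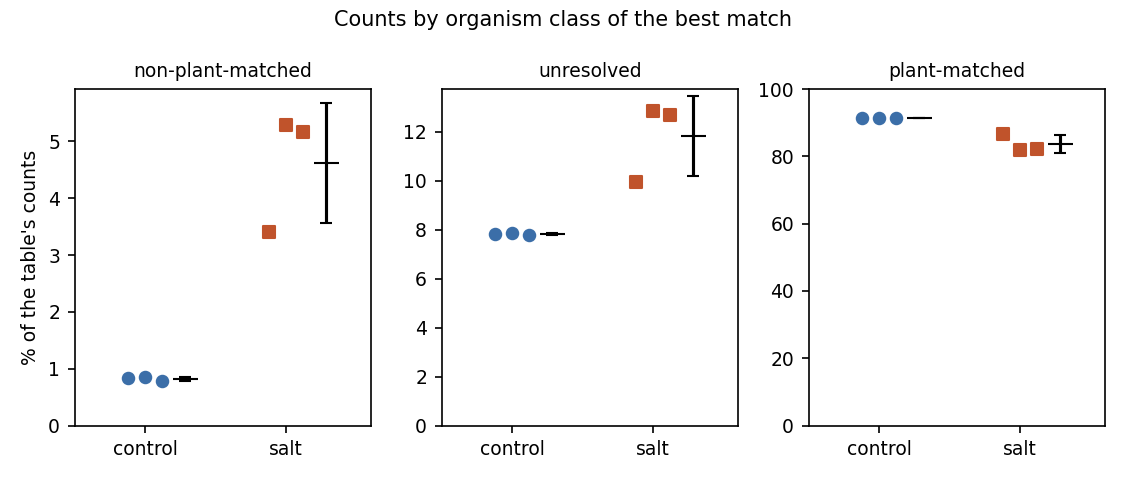
Share of the regulator table's counts, in percent, in clusters grouped by the organism of their best match, with 1 point per library and the mean with SD beside them. The salt libraries hold 3.40% to 5.29% non-plant-matched counts, all above the control libraries, whose mean is 0.819%.

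Most tested jasmonate signalling clusters, largely TIFY (JAZ) proteins that repress jasmonate responses, rose. Of 72 tested members 46 rose, 3 fell and the rest did not pass (48 and 3 adjusted over the list alone), with a median log2 fold change of 1.52 (camera adjusted p = 1.6e-09, and adjusted p = 0.21 with an estimated correlation). Under the plant-matched scaling 49 of 67 rose and 1 fell, with a median of 1.98 (camera adjusted p = 2.0e-14, estimated-correlation adjusted p = 0.11). A further TIFY 7 cluster (Cluster-71316.116890) rose from 8.87 ± 0.700 to 57.6 ± 7.03 CPM, with a log2 fold change of 2.70 (SE 0.12; edgeR adjusted p = 6.6e-05). TIFY 10A (Cluster-71316.160620), the most abundant of those named, rose from 222 ± 4.79 to 608 ± 71.3 CPM, a log2 fold change of 1.45 (SE 0.09; edgeR adjusted p = 1.0e-04). TIFY 6B (Cluster-71316.157808) rose by 0.66 on the log2 scale (SE 0.07; edgeR adjusted p = 6.4e-04) and by 1.18 under the plant-matched scaling. The deposited Tify family, which shares most of these clusters, had 36 of 62 higher and 3 lower (camera adjusted p = 2.3e-06, estimated-correlation adjusted p = 0.27).

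Of clusters for histones, the proteins that package DNA, more rose than fell. In the list of histones and cell cycle genes 86 of 174 tested clusters rose and 30 fell (89 and 30 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 4.7e-05, estimated-correlation adjusted p = 0.12). Under the plant-matched scaling 52 of 116 rose and 9 fell, with a median of 0.55 (camera adjusted p = 0.0012, estimated-correlation adjusted p = 0.25). The list also caught chromatin enzymes whose annotation mentions histones. Matched to protein names alone, which was added after seeing the data, 42 of 55 plant-matched members rose and 0 fell by edgeR. All 12 non-plant-matched members rose, beside the rise in the share of such counts from 0.819% to 4.62%. Histone H2A.1 (Cluster-71316.173270) had a log2 fold change of 1.68 (SE 0.09; edgeR adjusted p = 7.7e-05), and H2A.6 (Cluster-71316.200968), from 57.6 ± 3.01 to 92.0 ± 6.04 CPM, one of 0.68 (SE 0.08; edgeR adjusted p = 7.5e-04; n = 3) and of 1.20 under the plant-matched scaling. The histone methyltransferase ATX1 (Cluster-71316.136613), which deposits a mark of active genes, fell from 32.5 ± 1.84 to 5.96 ± 0.628 CPM.

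More auxin response clusters fell than rose. Of 161 tested, 6 rose and 78 fell (6 and 77 adjusted over the list alone), with a median of -1.14 (camera adjusted p = 7.4e-06, estimated-correlation adjusted p = 0.12). Among plant-matched clusters with their own scaling, 11 of 161 rose and 45 fell, with a median of -0.61 (camera adjusted p = 0.0071, estimated-correlation adjusted p = 0.15). The ARF family, which binds the promoters of auxin-regulated genes, had 1 of 65 higher, 38 lower and a median of -2.04 (camera adjusted p = 5.5e-06, estimated-correlation adjusted p = 0.070; plant-matched scaling 2 higher and 25 lower of 63). Auxin response factor 11 had a log2 fold change of -2.27 (SE 0.12; edgeR adjusted p = 7.9e-05), and 1 cluster of auxin response factor 2 (Cluster-71316.141319) one of -2.20 (SE 0.13; edgeR adjusted p = 9.5e-05). IAA9 (Cluster-71316.161819), a repressor of auxin responses, fell from 216 ± 11.4 to 104 ± 3.19 CPM, a log2 fold change of -1.06 and of -0.53 under the plant-matched scaling. Auxin response factor 6 (Cluster-71316.196367) fell by 0.53 on the log2 scale (SE 0.11; edgeR adjusted p = 0.0066), but its change was 0.00 under the plant-matched scaling.

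More clusters of the clock and cytokinin lists fell than rose. In the clock list 10 of 77 rose and 42 fell (10 and 43 adjusted over the list alone), with a median of -1.36 (camera adjusted p = 0.0039, estimated-correlation adjusted p = 0.12). Under the plant-matched scaling 9 of 71 rose and 28 fell (camera adjusted p = 0.0034, estimated-correlation adjusted p = 0.11). The clock-associated regulators APRR7 (Cluster-71316.155880) and APRR3 (Cluster-71316.142832) fell from 9.48 ± 1.30 to 1.44 ± 0.133 and from 27.6 ± 3.31 to 5.67 ± 0.828 CPM, with log2 fold changes of -2.71 (SE 0.20) and -2.28 (SE 0.15). The list also holds clusters of the cell differentiation protein RCD1, which is not a clock gene. The labels give the interval from treatment to collection but not the hour of collection. In the cytokinin list, which shares the APRR clusters, 16 of 97 rose and 43 fell (16 and 44 adjusted over the list alone), with a median of -1.05 (camera adjusted p = 0.033, estimated-correlation adjusted p = 0.12). That call was lost under the plant-matched scaling (camera adjusted p = 0.075; 15 of 90 higher and 33 lower), and under the scaling to all clusters it was lost without salt 3 (camera adjusted p = 0.072). ARR12 (Cluster-71316.175223), a response regulator that activates cytokinin-responsive genes, fell from 29.1 ± 2.38 to 6.72 ± 0.751 CPM, while ARR2 (Cluster-71316.132147) rose from 87.5 ± 5.09 to 105 ± 3.25, a log2 fold change of 0.27 (SE 0.06; edgeR adjusted p = 0.013; n = 3) and of 0.79 under the plant-matched scaling.

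Among regulators of nitrate and phosphate responses more clusters fell than rose. Of 116 tested, 7 rose and 53 fell (7 and 53 adjusted over the list alone), with a median of -0.98 (camera adjusted p = 8.1e-04, estimated-correlation adjusted p = 0.12). With the plant-matched scaling, 5 of 99 rose and 25 fell (camera adjusted p = 0.0086, estimated-correlation adjusted p = 0.17). NLP7 had a log2 fold change of -2.28 (SE 0.15; edgeR adjusted p = 1.2e-04) and 1 NLP6 cluster (Cluster-71316.204201) one of -1.71 (SE 0.12; edgeR adjusted p = 1.8e-04). An unresolved NLP6-like cluster (Cluster-71316.108635) rose by 0.88 on the log2 scale (SE 0.13; edgeR adjusted p = 0.0018) and by 1.41 under the plant-matched scaling. PHR1-LIKE 1 (Cluster-71316.166351), which acts in phosphate starvation, fell by 0.47 on the log2 scale, with 0.05 under the plant-matched scaling. In the gibberellin list 4 of 36 rose and 22 fell (4 and 22 adjusted over the list alone), with a median of -1.12 (camera adjusted p = 0.020, estimated-correlation adjusted p = 0.14; plant-matched scaling 3 higher and 10 lower of 29, camera adjusted p = 0.038, estimated-correlation adjusted p = 0.23). DELLA protein GAI (Cluster-71316.176719), a repressor of gibberellin responses, fell from 43.9 ± 2.98 to 17.4 ± 1.30 CPM (SD, n = 3). The abundant gibberellin-responsive protein CIGR1 (Cluster-71316.161524) had 291 ± 24.2 and 298 ± 19.04 CPM (edgeR adjusted p = 0.74; n = 3), but was called higher under the plant-matched scaling, with a log2 fold change of 0.56 (edgeR adjusted p = 0.0015).

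Members of groups best known from stress responses moved both ways. The median turned sign with the scaling for ERF, DREB/CBF, ABA-responsive and WRKY clusters, and moved close to 0 under the plant-matched scaling for NAC (-0.04) and for the list of salt and cold zinc fingers and WRKY factors (-0.0070; plant-matched members alone 0.014). In the ERF list 69 of 296 rose and 84 fell (68 and 84 adjusted over the list alone), with a median of -0.13 that turned to 0.17 with DESeq2 size factors, 0.10 with column sums and 0.42 with the plant-matched scaling (camera adjusted p = 0.67; plant-matched scaling 102 of 290 higher and 36 lower, camera adjusted p = 0.0036, estimated-correlation adjusted p = 0.11). DREB/CBF factors, which act in drought and cold responses, had 19 of 65 higher and 17 lower (19 and 17 adjusted over the list alone). Their median of -0.04 turned to 0.23, 0.16 and 0.47 under the same 3 scalings of all clusters (camera adjusted p = 0.66; plant-matched clusters alone 25 of 64 higher and 9 lower, camera adjusted p = 0.038, estimated-correlation adjusted p = 0.25). ABA-responsive regulators had 25 of 103 higher and 31 lower (25 and 31 adjusted over the list alone; camera adjusted p = 0.85). Their median of -0.39 turned to 0.13 with the plant-matched scaling, and plant-matched clusters alone had 32 of 101 higher and 13 lower (camera adjusted p = 0.074). The WRKY family had 22 of 224 higher and 83 lower, with a median of -0.56 that turned to 0.01 with the plant-matched scaling (camera adjusted p = 0.044, estimated-correlation adjusted p = 0.37; plant-matched clusters alone 49 of 214 higher and 41 lower). The NAC family, with 17 of 158 higher and 49 lower, did not pass (camera adjusted p = 0.065) and had 32 of 145 higher and 23 lower under the plant-matched scaling. Both results turned on single libraries, since the WRKY call was lost without salt 3 (camera adjusted p = 0.0505) and NAC passed without any 1 of the control libraries or salt 1 (0.032 to 0.043). WRKY6 (Cluster-71316.171431) fell from 150 ± 6.19 to 56.4 ± 3.49 CPM, while WRKY41 (Cluster-71316.88928) rose from 6.45 ± 0.659 to 21.3 ± 1.04 and WRKY40 (Cluster-71316.180529) from 179 ± 10.9 to 308 ± 19.1 (SD, n = 3; edgeR). In the list of salt and cold zinc fingers and WRKY factors 3 of 73 rose and 35 fell, also when adjusted over the list alone (camera adjusted p = 0.016, estimated-correlation adjusted p = 0.42), but 11 of 71 rose and 13 fell under the plant-matched scaling (camera adjusted p = 0.75). ZAT10 (Cluster-71316.158143), a zinc finger repressor known from salt stress, fell by 0.86 on the log2 scale (SE 0.07; edgeR adjusted p = 3.0e-04) and by 0.34 under the plant-matched scaling. Another ZAT10 cluster (Cluster-71316.164846) fell from 190 ± 5.30 to 132 ± 12.6 CPM, a log2 fold change of -0.53, but had -0.0070 under the plant-matched scaling (edgeR adjusted p = 0.93; n = 3).

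**Figure D3:**
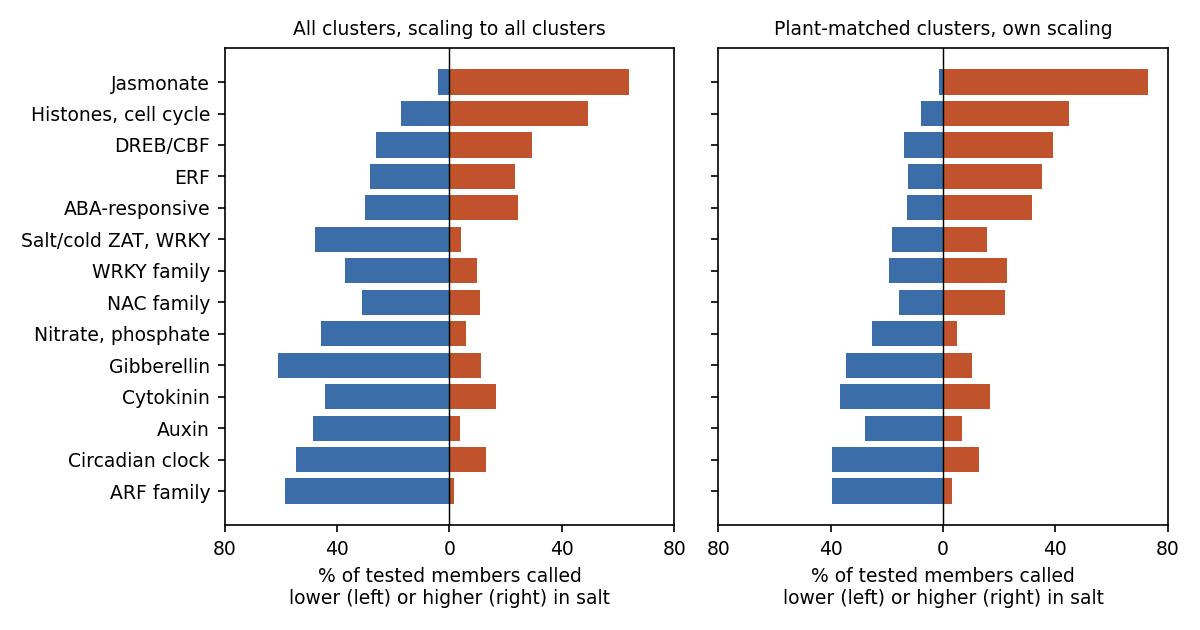
Percent of tested clusters of each list that edgeR called higher (right) or lower (left) in salt, for all clusters with the scaling to all clusters and for plant-matched clusters with their own scaling. Jasmonate and histone bars point mostly right and auxin and ARF bars mostly left in both panels, while the ERF bars (69 higher and 84 lower of 296, then 102 and 36 of 290) turn with the scaling.

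Of the 10 largest rises by fitted log2 fold change, 3 clusters had 0 counts in control and the others 1 or 2. Ethylene-responsive transcription factor 2 (Cluster-71316.152927) had 0 counts in control and 10.4 ± 1.81 CPM in salt, at least 189-fold higher, and prolyl 4-hydroxylase 7 (Cluster-71316.201865) 0 and 16.1 ± 6.28, at least 292-fold higher (SD, n = 3; bound from 3 counts over the control group). The histone methyltransferase specific for H3 lysine 9 (Cluster-71316.3046) was the only other plant-matched cluster among the 10 largest rises, with 2 counts in control and 160 in salt, a depth-scaled ratio of 104 (exact 95% counting interval 28.4 to 867). The remaining 7 were non-plant-matched or unresolved. All 10 of the largest falls were plant-matched and had 0 counts in the salt libraries. They included the histone demethylase LDL3 (Cluster-71316.185711; 20.1 ± 2.15 CPM in control, at least 280-fold lower), the calmodulin-binding activator CAMTA4 (Cluster-71316.162286; at least 148-fold lower) and auxin response factor 8 (Cluster-71316.202386; at least 106-fold lower). MYB86 (Cluster-71316.275291) was at least 83.6-fold lower, DOF2.5 (Cluster-71316.155318) at least 34.9-fold lower and REVEILLE 1 (Cluster-71316.61023) at least 32.4-fold lower. Other clusters of the same gene can carry its transcripts, so a cluster at 0 does not show that its gene is silent. The other clusters with the same NR match were summed under the plant-matched scaling. They moved the opposite way for LDL3 (log2 fold change signed by the cluster at 0, -1.06), CAMTA4 (-0.42), DOF2.5 (-0.20) and MYB86 (-0.18). They moved the same way for auxin response factor 8 (0.13), ethylene-responsive transcription factor 2 (0.82) and prolyl 4-hydroxylase 7 (8.60). Of 27 clusters with such values, 18 went the same way and 9 the opposite way. The summed clusters could themselves include clusters at 0 in a group. Another DOF2.5 cluster (Cluster-71316.166017) rose from 38.6 ± 1.48 to 79.2 ± 7.64 CPM (SD, n = 3; edgeR adjusted p = 2.9e-04).

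**Figure D4:**
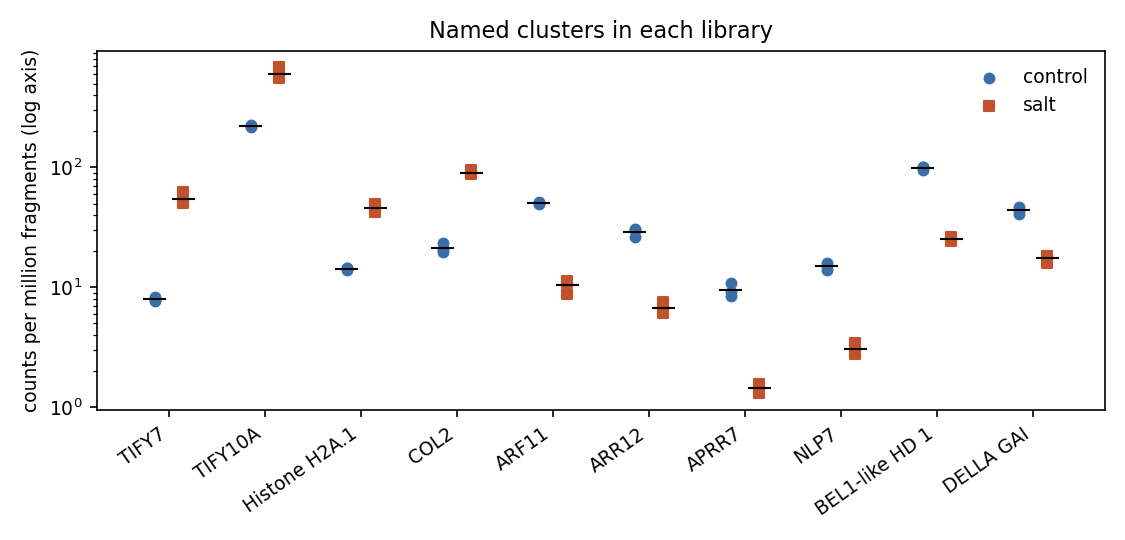
CPM, on a log axis, of 10 named clusters in each of the 3 control (circles) and 3 salt (squares) libraries, with bars at the means. The means in control and salt are, for example, 7.90 and 54.97 for TIFY 7 and 50.2 and 10.4 for auxin response factor 11.

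By family, camera at the preset correlation called 10 families higher and 12 lower. With plant-matched clusters alone it called 8 higher and 7 lower. With an estimated correlation none of these calls held under either scaling (lowest adjusted p = 0.065 among 71 families and 0.20 among 63). Under the scaling to all clusters that correlation lay below the preset 0.01 for some called families (ARF -0.0048, CCAAT -0.0020, HB -0.00039). It lay above for others (Tify 0.13, Zn-clus 0.22). A lost call therefore does not by itself show that the members moved together, since this test has low power with 6 libraries. At the preset correlation, families higher under both scalings were Tify, CCAAT, C2C2-GATA, CSD and HMG, and those lower under both were ARF, HB, RWP-RK, SBP and C3H. The RWP-RK family had 8 of 138 higher and 59 lower, but 5 of 93 and 23 among plant-matched clusters with their own scaling. The C3H call under the scaling to all clusters was lost without any 1 of the 6 libraries (camera adjusted p = 0.0502 to 0.11). The CCAAT family as deposited includes histones, and had 82 of 153 higher and 19 lower with a median of 1.00 (camera adjusted p = 7.5e-07, estimated-correlation adjusted p = 0.065; plant-matched scaling 46 of 94 higher and 4 lower). Of the homeodomain (HB) family, which holds developmental regulators, 14 of 134 rose and 63 fell, with a median of -0.90 (camera adjusted p = 0.0049, estimated-correlation adjusted p = 0.10; plant-matched scaling 8 higher and 31 lower of 103). BEL1-like homeodomain protein 1 (Cluster-71316.152225) fell from 99.0 ± 3.31 to 25.2 ± 1.11 CPM and ATHB-8 (Cluster-71316.148052), a regulator of vascular development, from 45.7 ± 2.67 to 12.1 ± 0.839 (SD, n = 3; edgeR). The fungal-type Zn-clus family had 91 of 118 higher and 0 lower by edgeR, with a median of 3.64 (camera adjusted p = 1.2e-20, estimated-correlation adjusted p = 0.26), and 37 of its 52 non-plant-matched clusters rose. By Fisher's exact test 11 families had more higher calls than other clusters, 8 had more lower calls, and under the plant-matched scaling 7 and 5 did. Fisher's exact test counts each cluster as independent, although clusters can be copies or alleles of 1 gene that share reads.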

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

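The tests of the share of other organisms and of the fall in plant-matched clusters were chosen after those results had been seen, as was the count of other splits of the libraries; those of clusters at 0 counts were set before their result was seen.

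Clusters whose best match is a fungus, oomycete, alga or protist took 4.62% of the regulator counts in the salt libraries and 0.819% in the control libraries, a signal outside the comparison of chrysanthemum genes. Of 9221 clusters with an NR match, 0 had a fungal one, so the class does not identify the source organism and can miss fungal RNA. Of the fungal-type Zn-clus family 91 clusters rose, of which 37 were non-plant-matched. Only 1 cluster of this family was plant-matched among those tested under the plant-matched scaling. Lower depth in salt argues little here, since a share does not change with depth and the lowest salt share was 4.01 times the highest control share. Plant transcripts matched to the wrong organism would move like other plant clusters. Under the plant-matched scaling the median log2 fold change of these clusters was 4.32, against -0.08 for plant-matched clusters, and 2.88 in the lowest salt library. But only 430 of the 1162 passed the filter, and clusters near 0 in control pass through their salt counts alone, which raises this median. Without the filter, their pooled counts scaled to depth were 4.82 times the control level, against 0.784 for plant-matched clusters. The classes were set after the counts per genus had been seen, so these values cannot exclude wrong matches. The pooled counts of the deposited Zn-clus family use neither the classes nor the filter. Scaled to depth, they were 4.38 times the control level, and every salt library lay above every control library. Plant-matched clusters of other families, such as Tify, also rose, so the rise of this family alone does not exclude wrong matches either. More RNA of other organisms in the salt libraries stays open. Among clusters that passed the filter, the median lay above 1 in 100% of the 23 families with at least 3 of them, from 2.58 to 5.57. The filter raises these medians too. Whether such RNA came with the treatment, the growing medium or the handling cannot be read from these libraries, and a biological effect of salt on organisms living on the roots may contribute but was not tested.

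Plant-matched clusters had a median log2 fold change of -0.63 under the scaling to all clusters and -0.08 under their own. The larger share of FPKM in the 10 most abundant clusters would lower the rest by a log2 ratio of -0.0295. The TMM factors behind the median of -0.63 already allow for such clusters, so this value cannot weigh a few abundant transcripts as a cause. Dilution of plant RNA as the whole cause of the lower calls is argued against, since 17.9% of plant-matched clusters were still called lower under their own scaling. Dilution as the cause of the median fall cannot be told apart from a fall in plant regulators, because the plant share of all RNA was not measured. In this table, which holds 2.29% of the clusters, the log2 ratio of the plant-matched share was -0.13.

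Of the plant-matched clusters with a mean count of at least 20, 35 had 0 counts in all 3 libraries of 1 group. Of these, 5 were higher and 30 lower in salt, and clusters with fewer counts were not included. If another copy or allele were read in the other group, the other clusters with the same NR match would move the opposite way; if the whole gene changed, they would move the same way. For 27 of them such other clusters existed and passed a minimum summed count. The median of their log2 fold change, signed by the direction of the cluster at 0, was 0.95 (95% bootstrap interval -0.18 to 1.58). The other clusters moved the same way for 18 and the opposite way for 9, of which 13 and 3 lay beyond 1. They could include further clusters at 0 in a group with the same NR match. The 27 values are then not independent, while the interval treats them as if they were. A switch between copies and a change of the whole gene cannot be told apart here, since the interval spans 0 and 1.

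The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05, and in each comparison 1 split, the real one, gave a result as large. The real split called 2810 regulator clusters, 1477 plant-matched clusters under their own scaling and 94476 clusters of the FPKM table. By edgeR and limma the highest of the other splits called 0 in each, with at most 35, 38 and 3524 at an unadjusted p under 0.05. Camera at the preset correlation called 22 families and 12 function lists in the real split and up to 13 and 8 in others, and never fewer than 9 and 3. Every other split mixes control and salt libraries on both sides. Part of the treatment difference then stays in the comparison, and the rest widens the spread within each side. The 0 calls of clusters and the calls by camera in those splits can follow from this, so they do not measure false calls. Fisher's exact test gave 19 families with more higher or lower calls, against a highest other of 0, where no cluster was called.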

How the results depend on the processing

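Alternatives that use organism classes, sums by NR match or protein names were chosen after seeing the data, the others before; where no reason is given, the cause was not tested. Regulator calls (1261 higher, 1549 lower) stayed within 1.5 times except for 1960 higher with the DESeq2 Wald test (which tested 9593 clusters), 829 lower with TMM over plant-matched clusters, and, with fewer features, 807 and 670 for plant-matched clusters alone, 746 and 703 for these without salt 1, and 656 and 652 for sums by NR match. Leaving out 1 library gave 1162 to 1371 higher and 1109 to 1635 lower. Of the calls in the FPKM table, the higher count moved to 68531 with FPKM above 0.3, which tested more clusters, and leaving out 1 library gave 37199 to 40085 higher and 41013 to 51438 lower.

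Families called by camera (10 higher, 12 lower) became 0 and 0 with an estimated correlation, 17 and 41 with fry, and 8 and 7 for plant-matched clusters; without 1 library they ranged from 9 to 11 higher and 9 to 19 lower, the most without control 2. Function lists (5 and 7) became 0 and 0, 8 and 14, and 4 and 4 in the same order. Families with more higher calls by Fisher's exact test (11) became 7 and those with more lower calls (8) became 5 for plant-matched clusters, and 5 with the replicate block.

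Same-numbered libraries did not deviate alike (correlations of deviations across clusters -0.0039, 0.0039 and -0.0034). No pairing by number was seen in these values, which cannot show whether samples were paired in growth or handling. The replicate block called 2144 regulator clusters, of which 2131 were among the 2810.

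Over the 121 named clusters, 1725 alternative values kept direction and side of the threshold, 42 fell short of it, 23 newly passed it and 25 reversed. With DESeq2 size factors, column sums and TMM over plant-matched clusters, HMGB1 (-0.11) went to 0.16, 0.094 and 0.41, HAT5 (-0.13) to 0.15, 0.081 and 0.39, HMG1/2-like (-0.04) to 0.23, 0.16 and 0.48, WLIM2b (-0.17) to 0.11, 0.036 and 0.35 and MBF1a (-0.17) to 0.11, 0.043 and 0.36. With TMM over plant-matched clusters alone, ARF6 (-0.53) went to 0.0025, PHL1 (-0.47) to 0.052, ASIL1 (-0.36) to 0.16 and WRKY33 (-0.50) to 0.025. CIGR1 (0.03) was called higher with DESeq2 size factors (0.31) and with the plant-matched TMM (0.56), and went to -0.0883 with no composition factor and -0.0884 with limma. Without 1 library CIGR1 ranged from -0.0209 (without salt 2; -0.017 without control 3) to 0.101, GRP2 (0.15) from -0.0209 (without salt 1) to 0.236, and HMG1/2-like from -0.108 to 0.0213 (without salt 2). Depth limits clusters with few counts, whose fold changes are bounds at 0 counts in a group and ratios with wide counting intervals at 1 to 3.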

Other observations

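Other regulators that the comparisons have not described also changed. GATA transcription factor 8 (Cluster-71316.161112) rose from 44.0 ± 4.42 to 108 ± 5.74 CPM and GATA26 (Cluster-71316.75183) fell from 23.3 ± 2.95 to 7.80 ± 0.307 (SD, n = 3; edgeR). A further GATA8 cluster (Cluster-71316.187789) had 41.6 ± 1.70 and 71.5 ± 28.4 CPM, with 39.8 in salt 1, and was not called (edgeR adjusted p = 0.062). Under the plant-matched scaling it was called higher, with a log2 fold change of 1.32 (edgeR adjusted p = 0.013). CONSTANS-LIKE 2 (Cluster-71316.228937), whose best match is a chrysanthemum protein, rose from 21.3 ± 1.91 to 90.7 ± 3.17 CPM, a log2 fold change of 2.09 (SE 0.09; edgeR adjusted p = 4.5e-05). In the SBP family 0 of 31 clusters rose and 15 fell by edgeR, with a median of -1.53 (camera adjusted p = 0.0049, estimated-correlation adjusted p = 0.23). Among plant-matched clusters with their own scaling 0 of 30 rose and 8 fell, with a median of -1.10 (camera adjusted p = 0.024). SPL7 (Cluster-71316.114695), a regulator of copper responses, fell from 37.5 ± 2.19 to 15.1 ± 0.780 CPM. The heat shock factors HSF24 (Cluster-71316.153183) and HSF30 (Cluster-71316.220650) had log2 fold changes of 0.66 (SE 0.11) and -2.60 (SE 0.26). Of the 3 annotated clusters with the highest mean level, 2 matched the CCCH zinc finger protein C3H29 and 1 the high mobility group protein HMGB1. The C3H29 cluster Cluster-71316.161248 fell from 652 ± 32.6 to 411 ± 21.2 CPM, with log2 fold changes of -0.67 and of -0.14 under the plant-matched scaling. The other, Cluster-71316.162139, had -0.82 and -0.30. A less abundant C3H29 cluster (Cluster-71316.156279) fell from 205 ± 12.8 to 48.2 ± 0.804 CPM, with -2.08 and -1.56 in the same order.

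Scarecrow-like GRAS proteins filled the endodermis and stele list, in which 11 of 133 rose and 53 fell (10 and 53 adjusted over the list alone; camera adjusted p = 0.024, estimated-correlation adjusted p = 0.35), but 26 of 129 rose and 20 fell under the plant-matched scaling. Scarecrow-like 30 (Cluster-71316.164388) fell from 124 ± 4.57 to 31.8 ± 2.12 CPM. Of the other tissue markers, the shoot and flower list had 24 of 117 higher and 33 lower (camera adjusted p = 0.93; among plant-matched clusters with their own scaling 25 of 111 and 14), and the photosynthesis list 3 of 24 higher and 10 lower (camera adjusted p = 0.34; plant-matched 1 of 18 and 3), the latter filled with regulators that are not photosynthesis genes. Root hair markers had 7 of 14 higher and 3 lower, but 6 of the 7 that rose were non-plant-matched, and 0 of 6 plant-matched members rose and 2 fell by edgeR. Xylem markers had 0 of 7 higher and 2 lower (plant-matched 1 of 6 and 2), and root meristem markers 3 of 28 and 7, which turned to 9 of 27 and 2 among plant-matched clusters. The camera adjusted p-values of these 3 lists were 0.22, 0.22 and 0.85, and 0.36, 0.75 and 0.21 among plant-matched clusters. Housekeeping controls had 41 of 119 higher and 37 lower, with a median of -0.33 that turned to 0.04 with DESeq2 size factors and 0.32 with the plant-matched scaling of all clusters. Of their 28 non-plant-matched members 25 rose, and plant-matched members alone had 12 of 72 higher and 17 lower, with a median of -0.46.

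The heat shock list had 12 of 22 higher and 3 lower (12 and 3 adjusted over the list alone; camera adjusted p = 0.020, estimated-correlation adjusted p = 0.14). Among plant-matched clusters it had 4 and 1 of 12 and the call was lost (camera adjusted p = 0.57), while its 3 non-plant-matched members all rose. The LEA and dehydrin list had 12 of 15 higher and 2 lower (12 and 2 adjusted over the list alone; camera adjusted p = 1.9e-04, estimated-correlation adjusted p = 0.20), but its members with the lowest p match fungal two-component stress proteins, and of its 3 plant-matched members 0 rose and 2 fell by edgeR. The list of microbial and virus sequences had 375 of 649 higher and 79 lower (383 and 86 adjusted over the list alone; camera adjusted p = 4.4e-16, estimated-correlation adjusted p = 0.12), and 44 and 21 of 171 among plant-matched clusters. Lists not called under either scaling included abscisic acid synthesis and signalling with 0 of 11 higher and 5 lower (plant-matched 0 of 11 and 3; camera adjusted p = 0.086 and 0.36), brassinosteroid with 0 of 15 and 6 (plant-matched 1 of 15 and 1), and ethylene with 4 of 17 and 8 (plant-matched 5 of 15 and 4). Calcium sensing had 3 of 14 higher and 5 lower (plant-matched 2 of 11 and 5), reactive oxygen enzymes 0 of 9 and 1 (plant-matched 0 of 9 and 0), and ion transport 8 of 21 and 4 (plant-matched 4 of 15 and 3), where the 5 non-plant-matched members all rose. Matched to protein names alone, abscisic acid synthesis and signalling was called lower under the scaling to all clusters, with 0 of 10 higher and 5 lower (camera adjusted p = 0.044 at the preset correlation, the only 1 run on that match), but not among plant-matched clusters (camera adjusted p = 0.25). Fewer than 5 members were tested for aquaporins, osmolytes, cell wall, ribosomal proteins and phenylpropanoids.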
